A study of Homo sapiens with 9 samples.

How the data were processed

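The series holds polyA RNA-seq of human cardiomyocytes from 9 libraries in 2 groups, 4 wild type and 5 RBPMS2-null. Per the labels' protocols, stem cells were differentiated in a monolayer with 6 µM CHIR99021 on days 0 to 2 and 5 µM IWR1 on days 4 to 5. Selection in 5 mM lactate began on day 12 and lasted 48 h, and collection was on day 15. Positive and negative magnetic columns in series then isolated cardiomyocytes, a purification aimed at removing other cells, and its purity was not measured here. Per the labels' protocols, polyA RNA went through a NEB Ultra II library preparation with 16 PCR cycles and was sequenced on a NextSeq 500 as 75-bp paired-end reads. The kit's strand setting, the annotation release and the treatment of duplicates are not given in the sources used here.

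The table, as deposited, holds estimated counts per gene, which are already whole numbers, and log2 values that are log2(TPM + 1). Whether the counts are Salmon estimates was inferred from the values and from Salmon in the submitters' processing notes. Those notes name Salmon 1.3, BWA 0.7.12-r1039 and bedtools 2.25.0, with the builds hg19, GRCh38 and hg38 and no roles. The deposited log2 values were turned back into TPM by removing the pseudocount of 1, and TPM sum to 1000000 in every library. The table has 60278 genes, of which 19736 had no count in any library, and 38306 have a gene symbol. Positions and GC content came from GENCODE release 29 (GRCh38), which matched 58072 of the genes by identifier (96.3%). The build of the deposited table is not given in the sources used here.

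Counts were tested with edgeR 4.0.16 under R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 19052 genes that passed the filter were tested, with a common dispersion of 0.0456 (coefficient of variation 21.4%). A log2 fold change is RBPMS2-null over wild type, with its SE. The 36 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and lists with at least 3 tested genes were adjusted together. The targeted gene was also tested with an exact permutation of group means over all splits into 4 and 5 libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 made the summaries and figures. On simulated counts with 200 planted genes, the edgeR test recovered 24% of genes changed by a log2 of 0.5, 72% at 1, 84% at 2 and 94% at 3, and 9 of 168 calls were false (5.4%). Camera called 1 list, the planted one. Simulated genes were drawn independently, so this does not check camera on correlated genes.

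Library totals ranged from 24934595 to 34035979, and 3 counts were worth 0.088 to 0.12 CPM. PCR reads have no molecular identifiers, so intervals and floors cover counting error only. No libraries were identical: the chi-square per degree of freedom between 2 libraries was 5.83 to 63.39 in wild type, 9.48 to 78.89 in RBPMS2-null and 137.91 to 301.86 between groups. Some libraries lay in close pairs: wild-type 3 and 4 (5.83), 5 and 6 (11.03), and RBPMS2-null 9 and 10 (9.48), 7 and 8 (18.32). Whether close libraries shared a culture is not given, so the number of independent samples may be smaller. All 9 libraries were used, as separate samples.

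Group assignments, the test, the lists, the other settings to try and the rule for named genes were set before the data were examined. Named genes were RBPMS2 and RBPMS, the 12 largest increases and 12 largest decreases, 5 further genes with the smallest adjusted p, and up to 4 members of each list with the smallest p. The increases, decreases and further genes needed an adjusted p under 0.05, a proper gene symbol, non-overlapping groups and a mean of at least 5 TPM in the higher group. Other genes are named only where stated. Some genes that the rule selects are not reported here. Lists on sarcomere, ion channels, metabolism, stress, signalling, splicing, imprinting and other cell types came from textbook knowledge, and none was chosen on these samples. Other settings chosen then were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), no filter, a strict filter, mitochondrial genes left out, each library left out, an adjusted p under 0.01, a test against a log2 change of 0.5, an estimated correlation and fry. Settings for a table without counts were not needed. Alternatives chosen after seeing the data were library subsets, sums of the closest libraries, scaling to filament genes, and removal of the GC trend of each library in 20 bins of the GC content of each gene's longest transcript (98.5% of tested genes had a value).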

Results

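Polyadenylated RNA was sequenced from cardiomyocytes made from human induced pluripotent stem cells. The parental line was WTC-11, a widely used human stem cell line, carrying Cas9 at 1 AAVS1 allele. Unedited cells (wild type, 4 libraries, numbered 3 to 6) were compared with cells lacking RBPMS2 on both alleles (RBPMS2-null, 5 libraries, numbered 6 to 10). RBPMS2 encodes an RNA-binding protein of heart and smooth muscle. Cells were collected on day 15 of a monolayer differentiation, after lactate selection and passage over positive and negative magnetic columns. Totals per library were 32641552, 32520848, 33819585 and 31864983 counts in wild type and 34035979, 30262008, 30578839, 24934595 and 31344464 counts in RBPMS2-null. All SDs below are over 4 wild-type and 5 RBPMS2-null libraries. Nothing in the labels states that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

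The comparison asks what changes in cardiomyocyte RNA when RBPMS2 is missing. The targeted gene itself (RBPMS2, ENSG00000166831, chromosome 15, 64739892 to 64775587, GRCh38) was read first, as a check of the labels. Its level was 112.7, 126.1, 107.4 and 111.7 TPM in the wild-type libraries and 39.8, 39.9, 34.2, 35.9 and 34.96 TPM in the RBPMS2-null libraries. The mean fell from 114.5 ± 8.06 to 36.9 ± 2.69 TPM. The edgeR fit of counts gave a 2.86-fold decrease (log2 fold change -1.52 ± 0.091 SE, adjusted p = 6.24e-07). Fold values here and below come from that fit unless given as bounds or count ratios, so they differ from ratios of mean TPM. The exact two-sided permutation test gave p = 0.016, the smallest p that the splits into 4 and 5 libraries allow. The direction matches the labels in all 9 libraries, although the level of an mRNA does not by itself check a null allele. On a scale set by the thick and thin filament genes, chosen after the data were seen, the RBPMS2 difference was 0.11 ± 0.25 SE, where the median of all genes was 1.60. The paralog RBPMS (chromosome 8, 30384479 to 30572261) fell from 369 ± 63.5 to 276 ± 57.8 TPM (log2 fold change -0.44 ± 0.13 SE, adjusted p = 0.016). Its group ranges overlapped, and its call was lost without wild-type library 4 (-0.33, adjusted p = 0.0509), without wild-type libraries 3 and 4 (0.244), without RBPMS2-null libraries 9 and 10 (0.102), with the closest libraries summed (0.122), with the GC trend removed (0.0865) and in the test against a log2 change of 0.5 (0.732).

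In RBPMS2-null cells 13 of 15 thick and thin filament genes, 11 of 16 cardiac transcription factors and 20 of 24 glycolysis genes were lower, while all 13 endoderm and liver markers, 24 of 28 cell cycle genes and 8 of 10 pluripotency markers were higher. MYH7 and MYL2 of the filament list were higher too, but both calls were lost in several alternatives, such as with the closest libraries summed (adjusted p = 0.069 and 0.154). Camera called these 6 lists at its preset correlation but not at an estimated one (adjusted p = 0.12 to 0.45). As many lists as in the real comparison were called in 35 of 100 splits of the libraries. Many of those splits held part of the group difference, so that share does not measure chance. MYH6, the atrial-type myosin heavy chain of young cardiomyocytes, fell 4.34-fold, from 3844 ± 194 to 828 ± 229 TPM. TNNT2, cardiac troponin T, fell 3.75-fold, from 5461 ± 650.3 to 1301 ± 163 TPM. AFP, the fetal serum protein of liver and yolk sac, rose from 1.92 ± 0.247 to 2412 ± 1486 TPM (log2 fold change 10.25 ± 0.69 SE, adjusted p = 4.69e-06). TOP2A, a topoisomerase of dividing cells, rose 5.20-fold, from 17.8 ± 4.06 to 75.3 ± 9.40 TPM.

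**Figure D1:**
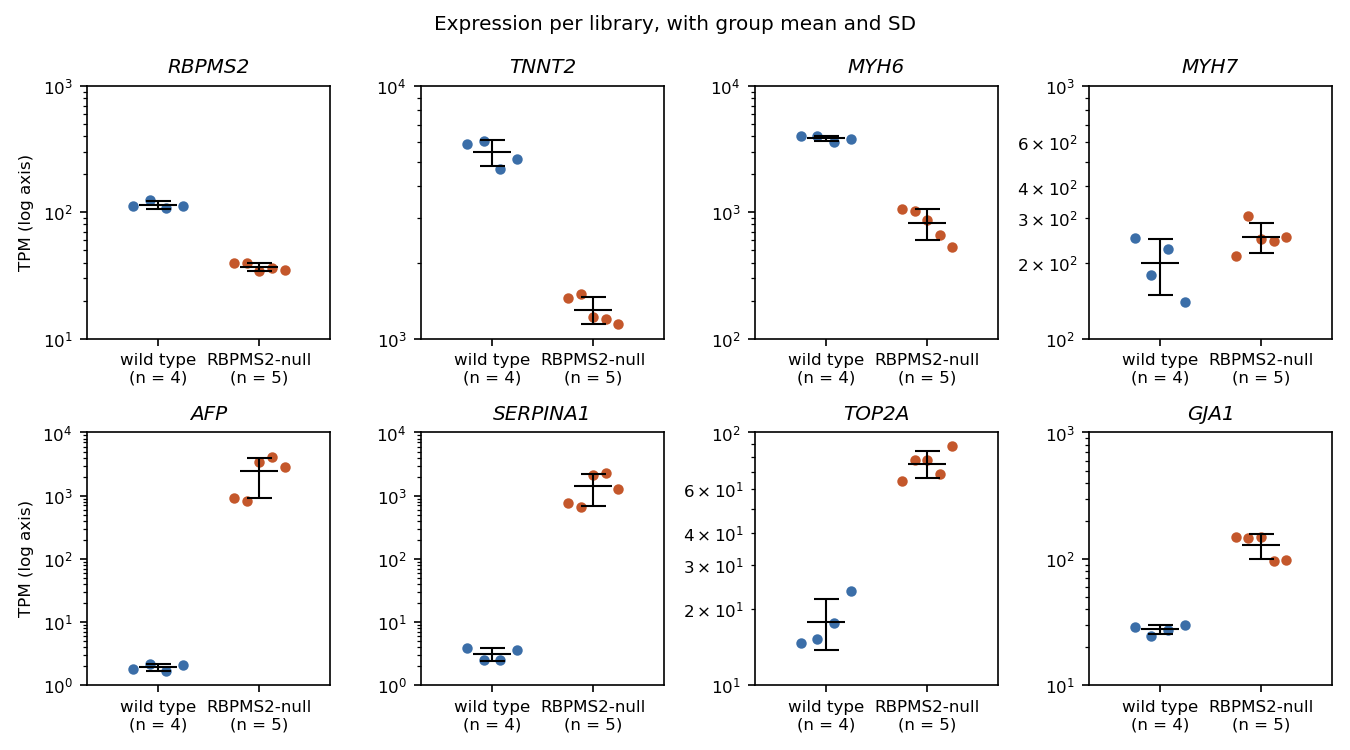
Expression of 8 genes in TPM on log axes, with each point a library, the wide tick the group mean and the whiskers 1 SD (4 wild-type, 5 RBPMS2-null libraries). TNNT2 and MYH6 lay lower and AFP, SERPINA1, TOP2A and GJA1 higher in every RBPMS2-null library than in any wild-type library, whereas MYH7 ranges overlapped.

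Of 19052 genes tested with edgeR's quasi-likelihood test, 10785 (56.6%) changed at an adjusted p under 0.05, 5517 higher and 5268 lower in RBPMS2-null cells. Counts of list members called below are given by direction, so each should be read against 5517 higher or 5268 lower of 19052 genes. A list near those shares in both directions does not stand out from all genes. The balance depended on the scale: limma-trend gave 2809 higher and 5733 lower, and the scale set by filament genes 16319 and 167. Changes of at least 2-fold were found in 4018 genes, 2374 higher and 1644 lower. The 2 groups did not overlap in 7990 genes (41.9% of those tested), where chance gives 1.6% if all 9 libraries are independent. Some libraries lay in close pairs, so the share by chance may be higher. Fewer genes, 6602, changed after the closest libraries were summed into 2 and 3 samples, and 4885 passed a test against a log2 change of 0.5. Median log2 fold change also fell with transcript GC content, from 0.49 in the lowest-GC bin to -0.71 in the highest, and 8680 genes changed after that trend was removed, 6878 of them shared with the same direction and 111 with the opposite.

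**Figure D2:**
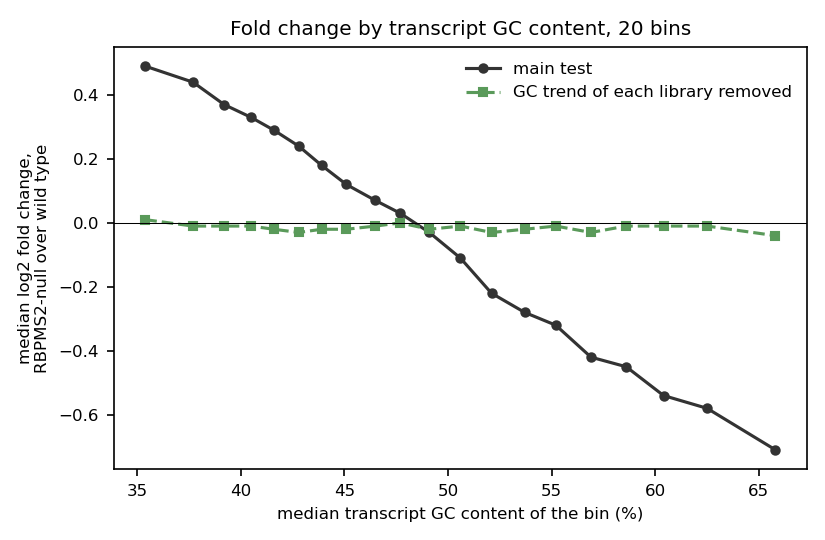
Median log2 fold change of RBPMS2-null over wild type in 20 bins of transcript GC content, for the main test (circles) and after the GC trend of each library was removed (squares). In the main test the medians ran from 0.49 at 35.4% GC to -0.71 at 65.8% GC, and after removal they lay close to 0.

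All 15 genes of the thick and thin filament list changed, 13 lower and 2 higher (median log2 fold change -1.70, camera adjusted p = 1.42e-08; adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, the counts were also 13 and 2. MYBPC3, cardiac myosin-binding protein C, fell 4.22-fold and TNNI1, slow skeletal troponin I, 2.80-fold. The 2 that rose were MYH7, from 199 ± 49.4 to 252 ± 33.8 TPM (adjusted p = 0.0256), and MYL2, from 3.42 ± 1.00 to 5.78 ± 2.26 TPM (adjusted p = 0.037). Both encode ventricular-type myosin subunits, and MYL2 was chosen after its values were seen. The call of MYH7 was lost without wild-type library 4 (adjusted p = 0.0652), without RBPMS2-null library 7 (0.0511) or 10 (0.0502), with limma-trend (0.0785), with no filter (0.0834), in the test against 0.5 (0.51) and with the closest libraries summed (0.069). It was also lost without wild-type libraries 5 and 6 (0.127), RBPMS2-null libraries 9 and 10 (0.0988) or 6, 7 and 8 (0.115). The call of MYL2 was lost without wild-type library 4 (0.0906), 5 (0.0862) or 6 (0.0987), without RBPMS2-null library 9 (0.0808) or 10 (0.0896), with limma-voom (0.0546), with limma-trend (0.0617), in the test against 0.5 (0.147) and with the closest libraries summed (0.154). It was also lost without wild-type libraries 3 and 4 (0.052) or 5 and 6 (0.236) and without RBPMS2-null libraries 9 and 10 (0.271). Neither passed an adjusted p of 0.01. In the Z-disc, M-band and titin filament list, 24 of 31 genes fell, 1 rose and 6 did not pass, with 25 lower and 1 higher adjusted over the list alone (median -1.12, camera adjusted p = 1.48e-09; adjusted p = 0.30 with an estimated correlation). LDB3, a Z-disc protein, fell 3.11-fold and DES, the muscle intermediate filament desmin, 7.07-fold. In the same libraries the endoderm and liver markers averaged 0.94 to 1.55 on the log2(TPM + 1) scale in wild type and 5.02 to 6.51 in RBPMS2-null.

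Cardiac transcription factors fell in 11 of 16 genes and rose in 0 (median -0.97, camera adjusted p = 1.48e-09; adjusted p = 0.12 with an estimated correlation), with the same 11 and 0 adjusted over the list alone. TBX20 fell from 77.9 ± 7.78 to 21.9 ± 3.42 TPM, HAND2 from 222 ± 31.2 to 36.5 ± 6.32 TPM and TBX5 from 132 ± 8.40 to 23.2 ± 4.70 TPM. Of 28 ion channel and conduction genes, 17 fell, 4 rose and 7 did not pass, and the counts adjusted over the list alone were 17 and 4 (median -0.79, camera adjusted p = 0.0015; adjusted p = 0.25 with an estimated correlation). HCN4, the pacemaker channel, fell 5.68-fold, KCNJ3, a subunit of an atrial potassium channel, fell 16.1-fold, and GJA1, connexin 43, rose 5.61-fold from 27.5 ± 2.20 to 127 ± 28.3 TPM. Atrial markers fell in 8 of 13 genes and rose in 2 (8 and 2 adjusted over the list alone; median -1.39, camera adjusted p = 2.87e-04; adjusted p = 0.29 with an estimated correlation). Pacemaker markers fell in 7 of 10 genes and rose in 3, also adjusted over the list alone (median -2.17, camera adjusted p = 0.0013; adjusted p = 0.29 with an estimated correlation). CACNA1G, a T-type calcium channel, fell 11.5-fold. The ventricular list was not called (3 higher, 2 lower, 3 not passing; camera adjusted p = 0.17), and its median of 0.18 and mean of -0.20 differ in sign. LBH, a transcription cofactor of that list, fell from 393 ± 24.4 to 63.0 ± 13.4 TPM. Endoderm markers were higher in the same RBPMS2-null libraries, at 5.02 to 6.51.

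**Figure D3:**
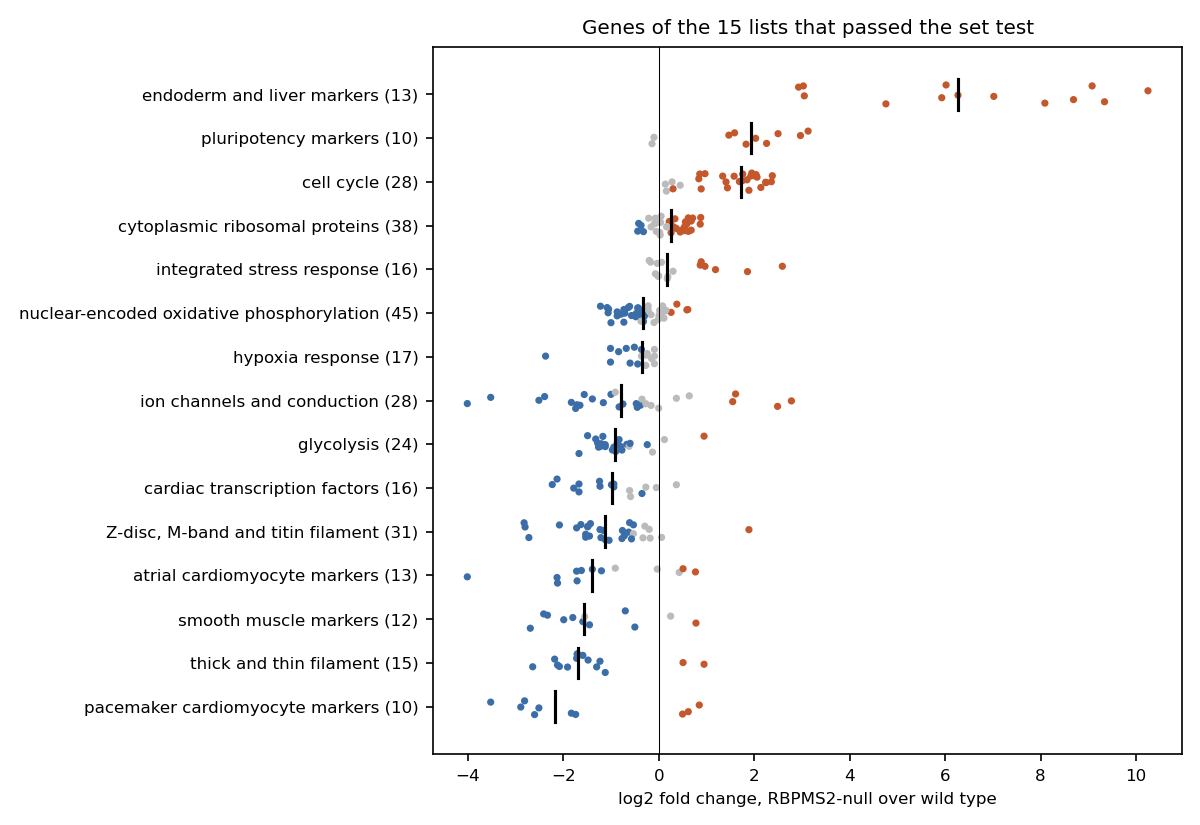
Log2 fold change, RBPMS2-null over wild type, of each tested gene in the 15 lists that passed the set test, with orange points for genes that rose, blue for genes that fell, grey for genes that did not pass and a black tick at the list median. Number of tested genes is in brackets; medians ran from -2.17 for pacemaker markers to 6.27 for endoderm and liver markers.

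Glycolysis genes fell in 20 of 24 cases and rose in 1, also adjusted over the list alone (median -0.92, camera adjusted p = 2.92e-09; adjusted p = 0.30 with an estimated correlation). ALDOC and ENO3, the aldolase and enolase forms of brain and muscle respectively, fell 3.18-fold and 2.40-fold. Nuclear-encoded oxidative phosphorylation genes fell in 25 of 45 cases, rose in 4 and did not pass in 16, with the same 25 and 4 adjusted over the list alone (median -0.33, camera adjusted p = 6.59e-04; adjusted p = 0.60 with an estimated correlation). ATP5F1D, a subunit of ATP synthase, fell 2.32-fold. Of 17 hypoxia response genes 9 fell and 0 rose, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0081; adjusted p = 0.25 with an estimated correlation). ADM, which encodes adrenomedullin, fell 5.16-fold. Mitochondrially encoded mRNAs were higher in 8 of 13 genes (10 adjusted over the list alone) but the list was not called in the main test (camera adjusted p = 0.053). It was called with DESeq2 (0.0496), limma-trend (0.0246), no filter (0.00423), fry (0.0456) and the closest libraries summed (0.0415), and without wild-type library 4 (0.0381), wild-type libraries 3 and 4 (0.0302), RBPMS2-null library 7 (0.00331) or 8 (0.0289), or RBPMS2-null libraries 6, 7 and 8 (1.60e-04). Mitochondrial genes took 14.9 ± 0.44% of counts in wild type and 21.9 ± 2.74% in RBPMS2-null libraries. Endoderm markers were higher in the same RBPMS2-null libraries, at 5.02 to 6.51.

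All 13 tested endoderm and liver markers rose, also adjusted over the list alone (median 6.27, camera adjusted p = 2.84e-16; adjusted p = 0.25 with an estimated correlation). SERPINA1, alpha-1 antitrypsin, rose from 3.11 ± 0.723 to 1427 ± 754 TPM, and TTR, transthyretin, from 0.591 ± 0.352 to 64.6 ± 15.6 TPM. AFP was 922, 824, 3356, 4160 and 2799 TPM in RBPMS2-null libraries 6 to 10. Further increases were in fibrinogen genes, FGG from 0.102 ± 0.111 to 40.0 ± 28.7 TPM and FGB from 0.424 ± 0.349 to 154 ± 88.1 TPM. ITIH2, AMBP and FGA, all genes of secreted liver proteins, had log2 fold changes of 9.35, 9.23 and 9.35 (AMBP 9.93 without wild-type library 6). Genes with 0 counts in every wild-type library give lower bounds against a floor of 3 counts per library: KNG1 was at least 160-fold higher, CYP3A7 at least 224-fold higher and ORM1 at least 36.0-fold higher. CYP3A7 and ORM1 have close paralogs that could share their reads, so both are uncertain. TM4SF4 had 3 counts in wild type, a ratio of 711 (95% exact interval 243 to 3450, counting error only), and its log2 fold change of 9.36 was 10.24 without wild-type library 5.

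Cell cycle genes rose in 24 of 28 cases and fell in 0, with 25 adjusted over the list alone (median 1.72, camera adjusted p = 2.11e-20; adjusted p = 0.25 with an estimated correlation). UBE2C and CCNB1, both needed for mitosis, rose 3.85-fold and 4.10-fold. PRR11, outside the lists, rose 4.49-fold. Pluripotency markers rose in 8 of 10 genes and fell in 0, also adjusted over the list alone (median 1.93, camera adjusted p = 0.0024; adjusted p = 0.45 with an estimated correlation). LIN28B, a regulator of let-7 processing, rose 2.77-fold and SOX2, which neural cells also express, from 5.01 ± 4.12 to 37.7 ± 6.63 TPM. The 2 that did not pass, named after their values were seen, were POU5F1, at 0.527 ± 0.253 and 0.476 ± 0.364 TPM (adjusted p = 0.87), and DNMT3B (0.58). Cytoplasmic ribosomal protein genes rose in 21 of 38 cases, fell in 4 and did not pass in 13, as adjusted over the list alone (median 0.26, camera adjusted p = 0.0075; adjusted p = 0.61 with an estimated correlation). That call was lost without RBPMS2-null libraries 6, 7 and 8 (adjusted p = 0.147). RPS6 rose 1.82-fold. Integrated stress response genes rose in 6 of 16 cases and fell in 0, also adjusted over the list alone (median 0.18, camera adjusted p = 0.033; adjusted p = 0.56 with an estimated correlation). The members that moved were led by genes of serine synthesis and cystine import, PSAT1 (3.62-fold) and SLC7A11 (6.00-fold). The stress list lost its call without wild-type library 5 (adjusted p = 0.0605) and without RBPMS2-null library 6 (0.0526), 7 (0.0685) or 8 (0.0506), and without wild-type libraries 5 and 6 (0.0754), and without RBPMS2-null libraries 6, 7 and 8 its median was -0.12 (0.528). It averaged 4.12, 4.34 and 4.38 on the log2(TPM + 1) scale in those 3 libraries, but 3.84 and 3.70 in RBPMS2-null libraries 9 and 10 against 3.74 to 3.86 in wild type. Ribosomal protein genes averaged 10.68 and 10.69 in RBPMS2-null libraries 9 and 10, inside the wild-type range of 10.55 to 10.84. Endoderm markers were 6.51 and 5.90 in those 2 libraries, so neither group followed them there.

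Smooth muscle markers fell in 9 of 12 genes and rose in 1, also adjusted over the list alone (median -1.57, camera adjusted p = 0.02; adjusted p = 0.60 with an estimated correlation). SYNPO2, an actin-binding protein, fell 2.73-fold. The list lost its call without wild-type libraries 3 and 4 (median -0.42, adjusted p = 0.30), which averaged 6.79 and 7.01 on the log2(TPM + 1) scale against 5.43 and 5.58 in libraries 5 and 6. It was also lost without RBPMS2-null libraries 9 and 10 (0.0554) or 6, 7 and 8 (0.0589). Endoderm markers were higher in the same RBPMS2-null libraries, at 5.02 to 6.51 against 0.94 to 1.55. Markers of other cell types were not called in the main test: fibroblast and matrix 4 higher and 6 lower of 14 (5 and 6 adjusted over the list alone, camera adjusted p = 0.36), endothelial 2 and 3 of 8 (0.22), epicardial 2 and 6 of 9 (0.52), neural 4 and 1 of 9 (0.16) and skeletal muscle 0 and 2 of 5 (0.27). Fibroblast markers also depended on the wild-type pair, with a median of -0.77 without wild-type libraries 5 and 6 (called, adjusted p = 0.0161) and 0.96 without 3 and 4 (0.768), and the endothelial median turned to 0.14 without 3 and 4 (0.394) and to 0.69 with no filter (0.175). Neural markers were called with no filter (0.0119), without wild-type libraries 3 and 4 (0.0448) and without RBPMS2-null libraries 9 and 10 (0.0339). PDGFRA, a receptor of mesenchymal cells, fell 5.05-fold and KDR, the endothelial VEGF receptor, 4.85-fold.

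The other lists were not called in the main test, and their counts adjusted over the list alone were the same unless given. Calcium handling had 5 genes higher and 14 lower of 30 (camera adjusted p = 0.053). RYR2, the calcium release channel, was 2.30-fold lower in the fit of counts. Its level was 53.35 ± 1.72 TPM in wild type and 31.9 ± 5.17 TPM in RBPMS2-null. Intercalated disc genes had 3 higher and 7 lower of 14 (0.54), maturation markers 5 and 7 of 16 (0.16) and stress and natriuretic genes 2 and 6 of 12 (0.36). Fatty acid oxidation had 5 and 10 of 26 (0.33), cholesterol synthesis 2 and 7 of 17 (0.053), p53 targets 9 and 2 of 17 (0.082) and immediate early genes 7 and 0 of 17 (0.16). Endoplasmic reticulum chaperones had 5 and 2 of 16 (5 and 1 adjusted over the list alone; 0.42), SR proteins and hnRNPs 8 and 2 of 23 (0.17) and imprinted genes 7 and 3 of 17 (0.57). In 3 lists the median and mean or test differed in sign: interferon response, 4 and 5 of 12 (median -0.12, mean 0.22, camera adjusted p = 0.75), BMP and TGF-beta genes, 7 and 10 of 26 (0.03, -0.09, 0.28), and muscle-related splicing regulators, 8 and 7 of 20 (-0.00, 0.43, 0.49). BMP2 fell 3.22-fold. Other settings called some of these lists. Calcium handling was called without wild-type library 5 (adjusted p = 0.0404) or 6 (0.0121) or both (0.00333), without RBPMS2-null library 7 (0.0429) or libraries 6, 7 and 8 (0.0196), and with DESeq2 (0.0496), no filter (0.00104), the closest libraries summed (0.0424), GC removal (0.00464) and fry (0.0016). Cholesterol synthesis was called without wild-type library 5 (0.0151) or 6 (0.0108) or both (4.21e-05), without RBPMS2-null library 6 (0.0391), and with DESeq2 (0.0496), limma-trend (0.0246), no filter (0.00235), a strict filter (0.0448), GC removal (0.0417) and fry (0.038). The p53 targets were called without RBPMS2-null library 10 (0.0429), libraries 9 and 10 (0.024) or wild-type libraries 3 and 4 (0.0399), and with no filter (0.0276), GC removal (0.0193) and fry (0.0016). Stress and natriuretic genes were called without wild-type libraries 5 and 6 (median -1.19, 0.00128) but had a median of 0.21 without 3 and 4 (0.892). Leaving out wild-type libraries 5 and 6 also called ventricular markers (0.0287), maturation markers (0.0286) and immediate early genes (0.0182). No filter called ventricular (0.0245) and maturation markers (0.0245) and BMP and TGF-beta genes (0.032). Maturation markers were also called without RBPMS2-null libraries 6, 7 and 8 (0.0196), and GC removal called intercalated disc (0.0338) and immediate early genes (0.00255). Fry called 15 lists beyond those of the main test.

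The largest decreases outside the lists were in GDF10, a secreted growth factor, from 10.3 ± 3.16 to 0.179 ± 0.0753 TPM (51.0-fold), HOXA4 (43.0-fold), OIT3 (29.6-fold) and DRD1 (20.2-fold). OSR1, a transcription factor of early mesoderm, fell from 43.8 ± 14.0 to 1.96 ± 1.17 TPM, CRHBP from 46.8 ± 22.6 to 2.49 ± 0.434 TPM and CCDC3 fell 16.3-fold. ASIC4 fell 19.6-fold and TRABD2B 14.7-fold. SPRR2F had 0 counts in RBPMS2-null libraries and was at least 30.7-fold lower. SPRR2F, with close paralogs, and the readthrough gene RPL36A-HNRNPH2 (15.2-fold lower) are uncertain because they could share reads with other genes. Leaving out 1 RBPMS2-null library moved some log2 fold changes: HOXA4 from -5.43 to -6.99 (library 10), OIT3 from -4.89 to -5.75 (library 6), DRD1 from -4.33 to -4.94 (library 9) and RPL36A-HNRNPH2 from -3.93 to -4.61 (library 10). The smallest adjusted p outside those sets was that of RNF207, which fell from 112 ± 6.73 to 16.6 ± 4.04 TPM (1.4e-07), followed by ADAM23 (5.38-fold lower, 1.52e-07). Endoderm markers were higher in the same libraries, at 5.02 to 6.51. The number of lists called, 15 of 36, was reached in 35 of 100 splits of the libraries. That share does not measure chance, because many splits held part of the group difference. Camera with an estimated correlation called 0 lists (5 at an unadjusted p under 0.05), where fry called 30.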

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

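The tests for single libraries that lie apart from their group were planned, and no test was chosen after these results were seen. Each highest or lowest library was compared with its nearest neighbour as a share of the group's range, in 135 groups of values, and 4 exceeded the 95% critical value where chance gives 6.8. For smooth muscle markers the RBPMS2-null group gave 0.909, because library 6 averaged 5.45 on the log2(TPM + 1) scale and the others 4.79 to 4.85. For neural markers the wild-type group gave 0.846, with library 5 at 1.01 and the others at 1.34 to 1.40. GDF10 gave 0.775 in the RBPMS2-null group, where library 8 had 0.0486 TPM from 3 counts and the others 0.190 to 0.235 TPM. PRR11 gave 0.719 in the RBPMS2-null group, where library 8 had 28.1 TPM and the others 24.5 to 25.4 TPM. No biological explanation was tested for these 4 values.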

How the results depend on the processing

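Settings chosen after seeing the data were the library subsets, the summed libraries, the scaling to filament genes and the GC removal; the cause of the changes below was not tested unless the setting shows it. No paired analysis was possible because the 2 groups share only 1 sample number. Leaving out each library in turn gave 9829 to 10509 genes changed, 3665 to 4291 changed at least 2-fold, 15 to 17 lists called, and -1.58 to -1.45 for RBPMS2. Genes changed numbered 4885 in the test against 0.5, 6602 with the closest libraries summed (fewer samples) and 16486 on the filament scale, where 14776 changed at least 2-fold, 99.0% of the changed genes were higher, the median of all genes was 1.60 and RBPMS2 was 0.11. Limma-trend gave 2357 genes at least 2-fold and 32.9% higher, against 51.2% in the main test, with a median of all genes of -0.18. Lists called were 23 with no filter, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 30 with fry. Of 165 named genes, 133 kept their direction and call under every alternative outside the filament scale in which they were tested. Most were picked on these same data for a large change or a small p, so this share does not describe genes in general.

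Lists that reversed were the following. Splicing regulators: 0.00 with RLE, 0.02 with upper quartile, 0.03 without RBPMS2-null 9 and 10 and 0.03 without 6, 7 and 8. Limma-trend: stress response -0.01, chaperones -0.13, immediate early -0.03, BMP and TGF-beta -0.18, SR proteins and hnRNPs -0.01. No filter: interferon 0.02, BMP -0.01, endothelial 0.69. With each library left out, splicing regulators ran from -0.09 to 0.01 (above 0 without wild-type 5) and interferon from -0.20 to 0.01 (above 0 without wild-type 5 or 6). Interferon was 0.01 without wild-type 5 and 6 and without RBPMS2-null 6, 7 and 8. BMP was -0.06 without wild-type 6, -0.02 without RBPMS2-null 8, -0.03 without wild-type 3 and 4 or 5 and 6, and -0.05 without RBPMS2-null 6, 7 and 8. Without wild-type 3 and 4: ventricular -0.04, stress and natriuretic 0.21, immediate early -0.08, fibroblast 0.96, endothelial 0.14. Integrated stress response was -0.12 without RBPMS2-null 6, 7 and 8. With GC removed: chaperones -0.02, interferon 0.04, BMP -0.10, SR proteins and hnRNPs -0.14, SEL1L -0.05, HNRNPD -0.01, TNNT1 0.28. SEL1L was -0.01 under limma-trend. GC removal gained calls for calcium handling (adjusted p = 0.00464), intercalated disc (0.0338), p53 (0.0193), immediate early (0.00255) and cholesterol (0.0417), and lost those of 8 named genes: RBPMS (0.0865), HSPB1 (0.0813), MT-ND3 (0.126), CRELD2 (0.0951), HNRNPH1 (0.423), SRSF11 (0.559), TIE1 (0.0778) and ACTN3 (0.1). The reversed SEL1L (0.541) and HNRNPD (0.928) lost theirs too; TNNT1 had none in the main test. In the simulation 24% of log2 changes of 0.5 were recovered. It changed only 200 single genes and 1 list, where 56.6% of genes changed in the real test. Adjusted p was therefore stricter in the simulation, and the share recovered does not measure the limit set by depth or the number of libraries.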

Other observations

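The tests on MYH7 and MYL2, on the genes that fell further than the filament genes, on the whole filament list, on the GC trend, on chamber markers and on RBPMS2 against filament genes were chosen after the results were seen; the tests on other cardiac genes, other cell types, chromosomes and splits were planned. Several genes outside the naming rule were chosen after their values were seen. Among splicing regulators ESRP1, of epithelial cells, rose 9.71-fold and MBNL3 11.3-fold, while RBM20, a cardiac splicing factor, fell 2.57-fold. Among epicardial markers TCF21 fell 22.9-fold and WT1 10.3-fold while ALDH1A1 rose 15.4-fold, and among imprinted genes DLK1 rose 4.10-fold from 84.7 ± 41.6 to 319 ± 158 TPM. Without wild-type library 4 the log2 fold change of TCF21 moved from -4.52 to -3.88 and that of WT1 from -3.37 to -2.74, and without wild-type libraries 3 and 4 they were -2.47 and -1.64. Without RBPMS2-null libraries 6, 7 and 8 the calls of TCF21 (adjusted p = 0.0537) and DLK1 (0.0702) were lost.

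The first pattern is the fall of cardiomyocyte genes with the rise of endoderm genes. A candidate explanation is a larger share of endoderm-like cells. Lactate selection and both columns were aimed at cardiomyocytes, but how far they removed such cells was not measured. AFP reached 2412 TPM and SERPINA1 1427 TPM. Of the 13 endoderm markers, 5 had at least 1 TPM in wild type and 0 stand in another list. In the planned test 7 of 105 other cardiac genes (6.7%) fell by over 0.5 more than the filament genes, under the bound of 10%, while 58 (55.2%) lay over 0.5 above them, so most did not fall by one common factor. The prediction allowed a smaller fall, as for genes that the added cells also express, and which genes those are was not tested. In a later test 2 of 15 filament genes differed from their list (the bound was 3), so neither share excluded dilution as the whole cause for these genes as a set; those 2, MYH7 and MYL2, lay at least 6.14 SE above the list, and a test limited to them was added only after that count of 2. That test restates why the 2 were picked and decides nothing, and whether the added cells express them was not tested. For a loss of cardiomyocytes with all other types raised alike, mean log2 fold changes of the lists were compared. The mean was 6.50 for endoderm, -0.36 for endothelial, -0.37 for fibroblast, -0.96 for epicardial and 1.10 for neural markers. The endoderm mean exceeded the others by at least 6.23 SE, but these SEs are over genes, which are not independent replicates. Fold changes also depend on the wild-type level, so the sizes of these differences decide nothing. The signs show that not all types rose alike in the main test, since the endothelial, fibroblast and epicardial means were below 0. None of those lists was called. Without wild-type libraries 3 and 4 the endothelial and fibroblast medians were 0.14 and 0.96, so their signs depended on that pair. A common factor gives no larger fall, and 7 genes fell further than the filament genes (weakest adjusted p = 0.0439). KCNJ3 (-2.30 ± 0.36 SE from them), CACNA1G (-1.99 ± 0.37 SE), DES (-1.18 ± 0.33 SE) and MYOM2 (-1.15 ± 0.36 SE) lay below every filament gene. The lowest filament gene was ACTA1 (-0.89 ± 0.56 SE). DES and MYOM2 lay below ACTA1 by less than its SE, so they were not told apart from it. For KCNJ3 and CACNA1G dilution is not the whole cause if the filament genes show the full factor, which was not tested. HCN4 (-0.86), KCNK3 (-0.71) and HAND2 (-0.58) lay within the range of the filament list, so dilution stays open for them. The comparison was not repeated with the GC trend removed. Dilution also stays open for the cardiac genes that did not fall further. Genotype cannot be told apart from culture or clonal differences because the labels name 1 RBPMS2-null line.

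The second pattern is a shift of chromosome medians, with chromosome 22 at -0.34, 13 at 0.32 and 19 at -0.31 from the autosomal median. A gain or loss in the edited line may produce such shifts, and the planned bound of 0.3 was passed (0.34). Median transcript GC was 56.3% on chromosome 22, 57.8% on 19 and 43.2% on 13. After the GC trend of each library was removed the largest deviation was 0.10, on chromosome 4, under that bound. These values argue against a gain or loss of a whole autosome that passes the bound, although the removal was chosen after the data were seen. Whether the GC trend is technical or follows the change in cell types was not tested.

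The third pattern is the lower RBPMS2 mRNA. It may share the fall of the filament genes, from which it differed by 0.11 ± 0.25 SE, so that explanation was not excluded. A lower amount of cardiomyocyte RNA and decay of an edited transcript both stay open, and the second was not tested. With the GC trend removed, the RBPMS2 log2 fold change was -1.09 ± 0.093 SE.

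A shift towards ventricular markers is a hypothesis for the rise of MYH7 and MYL2. The mean of 8 ventricular markers was -0.20 and that of 23 atrial and pacemaker markers -1.35, a difference of 1.15 (permutation p = 0.0502 across genes, two-sided, 100000 resamples). Genes are not independent replicates, and the 8 ventricular markers include MYH7 and MYL2, whose rise prompted the test. The test therefore decides nothing. Of 100 splits of the 9 libraries, the real one included, 1 gave as many genes as the real 10785. The highest other gave 6965, from a split that moved 1 RBPMS2-null library, number 6, to the wild-type side. For genes changed at least 2-fold, 1 split gave as many as 4018 (highest other 2173). In mixed splits the difference between the groups adds to the spread within them, and 97 of the 100 splits called 0 genes. The splits also treat all 9 libraries as exchangeable, although some lay in close pairs. The real split therefore stood out from the others, but a difference between cultures cannot be excluded as the cause. As many lists as 15 were called in 35 of the 100 splits (highest other 24). Many of those splits still divided the 2 groups unequally or kept close pairs together, so this share does not measure chance. It decides nothing about the number of lists, for which chance was not excluded.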
